A study of Mus musculus with 6 samples.

How the data were processed

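RNA was taken from a liver lobe of pups at postnatal day 10, and libraries were made from polyadenylated RNA with a kit that does not mark the strand. The 6 libraries fall into 2 genotypes, Jag1+/+ and Jag1Ndr/Ndr, with 3 libraries each, grouped by their labels. The deposited table gives whole read counts per gene entry, made by the authors without normalization and with 1 column per library. It also gives RPKM, which the authors multiplied by a TMM factor per library listed in the file header. The submitters' processing notes name STAR and the mouse genome mm10, with versions not given, and the read counter is not given in the sources used here. Dividing each deposited RPKM by its factor gave values proportional to reads over the library total within 5% for 98.0% of values over 9982 genes. Depth ranged from 12992592 to 59653111 reads per library, and a count of 0 allows up to 0.231 CPM in the shallowest and 0.0503 CPM in the deepest (3 reads), for counting error only.

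Which test to use was fixed before the data were examined, as limma on log2 RPKM or, if the deposited table also held counts, edgeR on those, and the counts were found and used. The alternatives, the gene lists and the rule for named genes were fixed at the same point, except where stated otherwise. Of 24489 gene entries, 13819 passed edgeR's filterByExpr. Besides these, 93 spike-in and eGFP entries with 5 reads in all were left out. Counts were scaled by TMM and tested with edgeR's quasi-likelihood test, in both directions, with Benjamini-Hochberg adjustment and a threshold of 0.05 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, R 4.3.3). Standard errors are the log2 fold change over the root of the F statistic. The common biological coefficient of variation was 0.243. Positions are those of RefSeq genes on GRCm38. A gene with 1 to 3 reads in a genotype is given as a ratio of rates with an exact Poisson interval.

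The 41 gene lists hold 646 genes, of which 643 matched an entry, 3 through an older symbol and 1 through an entry that joins several genes. Lists with at least 3 measured genes, except that of sex-linked genes, were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), and camera with an estimated correlation and fry were run beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone. Named genes are Jag1, then the 10 largest rises and 10 largest falls among genes past the threshold whose genotypes do not overlap and whose mean is at least 1 RPKM in the higher genotype, then up to 4 members of each list with the smallest adjusted p, and a fixed set of liver and bile duct genes. Not all of these are described here. Fasn, Acacb, Nr4a1, Igfbp2, Slc1a2, Abcg2, Abcb4 and Hsd3b7 lie outside this rule and were chosen after their values were seen, because their lists had 5 or fewer genes past the threshold in a direction. Sex was read from Xist and Y-linked reads.

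The alternatives were limma on the deposited RPKM with other pseudocounts, no filter or a stricter one, quantile normalization, rescaling to a common median, quality weights, robust moderation, a block for the replicate number, DESeq2, leaving out each library in turn and, for lists, an estimated correlation. A further 4 were added after the data were seen: limma on the deposited RPKM with a pseudocount of 0.5, the same with the header factors dividing, library totals without TMM, and a covariate for sex. The test was checked on simulated counts for 13819 genes with 200 planted changes. It recovered 31 of 100 genes changed 2-fold and 89 of 100 changed 4-fold, and called 17 of 13619 unchanged genes. Beside 31 and 89 true calls, the 17 false ones were a larger share than an adjusted p of 0.05 aims at.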

Results

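Polyadenylated RNA was sequenced from a liver lobe of mouse pups at postnatal day 10, with 3 libraries of the genotype Jag1Ndr/Ndr and 3 of Jag1+/+, on a C3H/C57bl6J background. Jag1 encodes a cell-surface ligand of Notch receptors, and the Nodder (Ndr) allele carries a missense mutation in it. Homozygous mice are used as a model of Alagille syndrome, in which intrahepatic bile ducts are scarce and bile flow is impaired. Reads over gene entries came to 17548954, 32326157 and 40499166 in Jag1+/+ replicates 1, 2 and 3, and to 12992592, 59653111 and 17478916 in Jag1Ndr/Ndr replicates 1, 2 and 3. Albumin (Alb) transcripts took 17.3%, 17.2% and 16.9% of the reads in the Jag1+/+ libraries and 13.03%, 10.3% and 10.95% in the Jag1Ndr/Ndr libraries. Xist reads numbered 9679 in Jag1+/+ replicate 1 and 32884 and 7252 in Jag1Ndr/Ndr replicates 2 and 3, and at most 29 in the other 3 libraries, which held reads of Y-linked genes, so that the sexes were unevenly spread over the genotypes. The first principal component of log2 CPM (counts scaled by library size) held 51.1% of the variance and parted the genotypes. Along the second, with 22.1%, the Jag1+/+ libraries lay between 2.14 and 7.35, while Jag1Ndr/Ndr replicates 1, 2 and 3 lay at 46.7, -43.6 and -19.9. The labels do not state that each library is a separate animal. Each genotype held libraries of both sexes, so more than 1 animal, but this does not show that all 3 libraries are separate. If some are not, part of the spread that the tests measure may be technical.

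The comparison asked which liver transcripts differed between Jag1Ndr/Ndr and Jag1+/+ pups. The lists of cholesterol synthesis, acute phase, neutrophil, macrophage, NRF2 target and immediate early genes were higher in Jag1Ndr/Ndr livers, and those of the growth hormone axis, hepatic transporters and pericentral enzymes lower, by camera with its preset correlation. These calls were all lost with an estimated correlation (smallest adjusted p = 0.290). Slpi, a secreted protease inhibitor, rose 112-fold, from 3.03 ± 0.455 to 343 ± 109 CPM (mean ± SD, n = 3 per genotype). Igfals, which stabilises circulating insulin-like growth factors, fell 8.39-fold, from 268 ± 56.1 to 32.0 ± 5.95 CPM. Of 13819 genes tested, 1054 changed, 653 being higher and 401 lower in Jag1Ndr/Ndr livers (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p under 0.05). The fitted change was at least 2-fold for 530 of the higher and 255 of the lower genes. In all 1054 of the changed genes the 3 libraries of a genotype lay apart from the 3 of the other, which held for 29.0% of the genes tested, where chance gives 10%. With 3 libraries per genotype the test favours such genes, so this is no separate support for the calls. Of 37 gene lists fixed in advance and tested with camera, 13 were higher and 6 lower. With an estimated correlation between genes camera called 0 of them (smallest adjusted p = 0.290; 5 at an unadjusted p under 0.05), and fry called 11, all among those that camera called with its preset correlation. The erythroid, mature hepatocyte, glycolysis and B cell lists did not pass by fry (adjusted p = 0.111, 0.0599, 0.0721 and 0.221). Nor did the megakaryocyte, extracellular matrix, clock and mesothelial lists (fry adjusted p = 0.221, 0.303, 0.211 and 0.221). A split that mixed the genotypes gave 5 and 16 lists by preset camera, so such counts alone do not mark the genotypes.

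The number of changed genes was 342, 282 and 319 without Jag1+/+ replicates 1, 2 and 3. Of these, 208, 155 and 181 were higher and 134, 127 and 138 lower. It was 1211, 1034 and 890 without Jag1Ndr/Ndr replicates 1, 2 and 3, and 596 with sex as a covariate. The drop was alike whichever Jag1+/+ library was left out, so it did not rest on a particular library. The Jag1Ndr/Ndr libraries differed more among themselves than the Jag1+/+ libraries did, and whether this lowered the counts was not tested. Higher genes made up 62.0% of the calls with TMM scaling, 74.3% of 816 with library totals alone and 79.3% of 469 in the deposited RPKM. The latter scalings raised log2 fold changes by a median of 0.13 and 0.22. The deposited RPKM were multiplied by factors by which edgeR divides, so calls of falls lost there may reflect that scaling. Log2 fold changes below are Jag1Ndr/Ndr over Jag1+/+, each with its standard error (SE), and CPM are means ± SD of 3 libraries per genotype.

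Jag1 itself (chromosome 2, positions 137081451 to 137116520 of GRCm38) measured 5.96 ± 0.807 CPM in Jag1+/+ and 4.84 ± 1.59 CPM in Jag1Ndr/Ndr livers, a log2 fold change of -0.28 ± 0.28 that did not pass (edgeR adjusted p = 0.638) and stood at 0.01 in the deposited RPKM with a pseudocount of 1. A missense allele need not alter its transcript level, so this value does not check the genotype labels. Heyl, a repressor downstream of Notch, fell from 18.8 ± 0.987 to 6.04 ± 3.06 CPM (log2 fold change -1.61 ± 0.34, edgeR adjusted p = 0.0279), the only 1 of 10 measured Notch target genes past the threshold, over all genes and adjusted over the list alone. Heyl had an edgeR adjusted p of 0.0856, 0.0911 and 0.0890 without Jag1+/+ replicates 1, 2 and 3. Heyl also lost its call in the deposited RPKM and with library totals alone. The Notch target Hes1 measured 24.8 ± 4.54 and 24.0 ± 11.6 CPM, and its log2 fold change of -0.03 ± 0.31 was 0.14 with library totals alone. The target list did not pass (camera adjusted p = 0.0981), but was lower without Jag1+/+ replicate 3 and Jag1Ndr/Ndr replicate 3 (adjusted p = 0.0172 and 0.00352) and with sex as a covariate. For Notch receptors, ligands and processing enzymes, edgeR gave 0 of 26 members past the threshold over all genes and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma with quality weights. Of these genes 1 rose without Jag1Ndr/Ndr replicate 2. That list did not pass either (camera adjusted p = 0.674, lower, and higher without Jag1+/+ replicate 2 or Jag1Ndr/Ndr replicate 1).

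Some biliary markers were higher in Jag1Ndr/Ndr livers and most did not pass. Cldn7 and Cldn4, which encode tight junction proteins, rose 14.2-fold and 17.96-fold, with log2 fold changes of 3.82 ± 0.38 and 4.17 ± 0.69 (edgeR adjusted p = 0.00238 and 0.0116). Ggt1, a gamma-glutamyltransferase, rose from 0.181 ± 0.0509 to 1.22 ± 0.672 CPM (edgeR adjusted p = 0.0262). These were the 3 of 25 cholangiocyte markers that passed over all genes, while 6 were higher and 1 lower adjusted over the list alone. Cldn4 lost its edgeR call without Jag1+/+ replicates 1, 2 and 3 (adjusted p = 0.0542, 0.0554 and 0.0555). Ggt1 had an edgeR adjusted p of 0.0794, 0.118, 0.113 and 0.0549 without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicate 3. The log2 fold change of Cldn4 moved from 4.17 to 3.28 without Jag1Ndr/Ndr replicate 3. Without Jag1Ndr/Ndr replicates 2 and 3, 1 and 2 markers were lower. Among the markers the number higher was 6 with quality weights and by DESeq2, and the number lower 1 with quality weights and without a filter, and 2 by DESeq2. The list did not pass (camera adjusted p = 0.273, higher, and lower without Jag1Ndr/Ndr replicate 3). Krt7 and Krt19, keratins of bile duct epithelium, had log2 fold changes of 0.55 ± 0.38 and 0.56 ± 0.50, and Sox9, a transcription factor of bile duct development, of -0.53 ± 0.44. Spp1 and Epcam stood at -0.83 ± 0.54 and -0.22 ± 0.60, the latter turning to between 0.02 and 0.17 without Jag1+/+ replicate 1 or Jag1Ndr/Ndr replicate 1 or 2. The adjusted p of these 5 genes lay between 0.425 and 0.883, but Spp1 passed without Jag1Ndr/Ndr replicate 3 (log2 fold change -1.89, edgeR adjusted p = 0.0131).

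**Figure D1:**
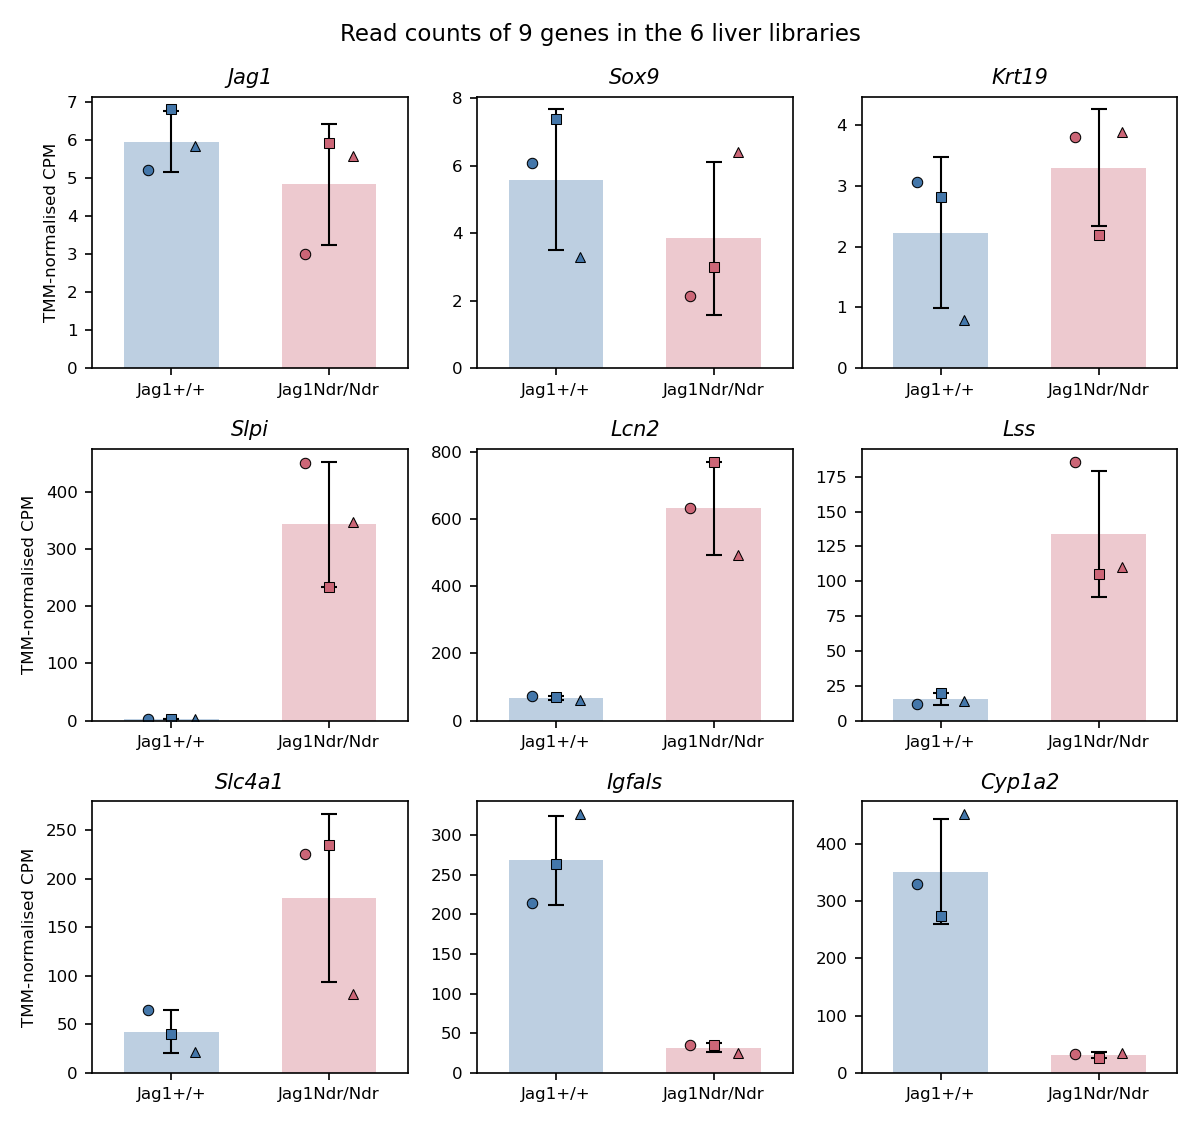
TMM-normalised counts scaled by library size (CPM, linear axes from 0) of 9 genes in the 3 Jag1+/+ and 3 Jag1Ndr/Ndr libraries, with bars for means, error bars for 1 SD, and circles, squares and triangles for replicates 1, 2 and 3. The genotypes overlap for Jag1, Sox9 and Krt19 and lie apart for the other 6 genes.

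Among the 10 largest rises, Slpi (chromosome 2, positions 164354070 to 164356507) had a log2 fold change of 6.81 ± 0.33 (edgeR adjusted p = 0.000221). Duox2, an oxidase of epithelial surfaces that makes hydrogen peroxide, rose from 0.0689 ± 0.0451 to 5.15 ± 1.72 CPM (edgeR adjusted p = 0.000941). Its maturation factor Duoxa2 had 2 reads over the Jag1+/+ and 227 over the Jag1Ndr/Ndr libraries, a ratio of rates of 97.2 (95% exact interval 26.6 to 808). Bpifb4 had 2 and 432 reads, a ratio of 185 (50.9 to 1533); such intervals cover counting error only. Nos2, the inducible nitric oxide synthase, rose 34.9-fold, Sprr1a, of the cornified envelope, 30.1-fold and Baiap2l2 40.4-fold, with edgeR adjusted p-values of 0.00227, 0.00140 and 0.00615. The trefoil peptide Tff3 rose 81.5-fold, unevenly between libraries (182 ± 196 against 2.16 ± 0.773 CPM), the trypsin inhibitor Spink3 29.4-fold and Sh3bgr 30.7-fold. Tff3 and Spink3 lost their edgeR calls without Jag1+/+ replicates 1, 2 and 3 (adjusted p = 0.0706, 0.0626 and 0.0619 for Tff3, and 0.0589, 0.0571 and 0.0569 for Spink3). Sh3bgr had an edgeR adjusted p of 0.0631 and 0.0570 without Jag1+/+ replicates 2 and 3. The log2 fold change of Tff3 moved from 6.35 to 5.04 without Jag1Ndr/Ndr replicate 1, that of Baiap2l2 from 5.34 to 4.70 without Jag1Ndr/Ndr replicate 3, and that of Sh3bgr from 4.94 to 5.65 and 4.33 without Jag1+/+ replicates 1 and 3.

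Among the largest falls, the carboxylesterase Ces3a (chromosome 8, positions 105048576 to 105061928) went from 159 ± 56.0 to 4.19 ± 1.69 CPM (log2 fold change -5.23 ± 0.40, edgeR adjusted p = 0.000880). Car3, a carbonic anhydrase, fell 24.3-fold, from 736 ± 240.1 to 30.1 ± 12.9 CPM, and Cyp26b1, which breaks down retinoic acid, fell 28.0-fold. The lipase-related Pnliprp1 fell 23.0-fold, A1bg 26.3-fold, the drug-metabolising Cyp2b10 20.8-fold, the protease inhibitor Mug1 19.9-fold and the angiotensin peptide receptor Mas1 19.6-fold. The edgeR adjusted p of these 7 genes lay between 0.00140 and 0.00663. Hamp2, a hepcidin paralog, had the most negative fitted value (-6.71 ± 1.59, edgeR adjusted p = 0.0408) and varied widely within Jag1+/+ livers (32.9 ± 48.8 CPM). Without Jag1+/+ replicate 1 the value was -3.70 ± 0.84, less negative than that of Ces3a. Hamp2 lost its edgeR call without Jag1+/+ replicates 1 and 2 and Jag1Ndr/Ndr replicates 1, 2 and 3 (adjusted p = 0.0697, 0.0518, 0.0879, 0.105 and 0.0799). Hamp2 also lost its call with quality weights (0.268), robust moderation (0.0926) and the header factors dividing (0.0653), and DESeq2 gave it no adjusted p. The log2 fold change of Mas1 moved from -4.29 to -5.03 without Jag1Ndr/Ndr replicate 3. Hamp2, Mug1, Ces3a and Cyp2b10 have close paralogs that can share reads, and Car3 and Mas1 overlap the noncoding genes Gm41999 and Airn, from which reads cannot be told apart without strand.

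The cholesterol synthesis list was higher (camera adjusted p = 3.2e-21; adjusted p = 0.290 with an estimated correlation). Of 25 measured members 21 rose over all genes and 22 adjusted over the list alone, and the others did not pass, with a median log2 fold change of 2.08. Lanosterol synthase Lss rose from 15.2 ± 4.38 to 134 ± 45.1 CPM (log2 fold change 3.13 ± 0.30, edgeR adjusted p = 0.00227), farnesyl diphosphate synthase Fdps 9.91-fold, the sterol dehydrogenase Nsdhl 8.59-fold and Dhcr7, of the last step to cholesterol, 4.43-fold. The number of list genes that rose was 13 without Jag1+/+ replicate 1. Lipogenic genes divided, 3 of 18 rising and 3 falling over all genes, 5 and 3 adjusted over the list alone. The fatty acid elongase Elovl6 rose 4.60-fold, and Fasn and Acacb, of fatty acid synthesis and chosen after their values were seen, rose 3.06-fold and 3.21-fold. Srebf1, a transcription factor of lipogenesis, fell 3.02-fold from 580.3 ± 59.5 CPM, Dgat2, of triglyceride synthesis, 1.94-fold and the elongase Elovl5 2.24-fold. Fasn and Dgat2 lost their edgeR calls without Jag1+/+ replicates 1, 2 and 3 (adjusted p = 0.0862, 0.0536 and 0.0899 for Fasn, and 0.0581, 0.0792 and 0.0593 for Dgat2). Acacb lost its edgeR call without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicate 3 (adjusted p = 0.0889, 0.101, 0.0956 and 0.0610). Elovl5 had an edgeR adjusted p of 0.0655 and 0.0745 without Jag1+/+ replicates 1 and 3. Acacb also lost its call with sex as a covariate and in the deposited RPKM, as did Dgat2 and Elovl5 in the deposited RPKM and with library totals alone. The lipogenesis list did not pass (camera adjusted p = 0.918, lower); its median of -0.04 and mean of 0.15 differ in sign, and its direction was higher with sex as a covariate, under quantile normalization and without Jag1+/+ replicates 2 and 3 and Jag1Ndr/Ndr replicate 3. With quality weights 5 lipogenic genes rose.

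Of 22 genes of fatty acid oxidation and PPAR alpha targets, 2 rose and 2 fell over all genes, and 3 and 3 adjusted over the list alone. The nuclear receptor Ppara fell from 343 ± 66.4 to 133 ± 52.3 CPM (log2 fold change -1.37 ± 0.31) and the acyl-CoA synthetase Acsl1 2.24-fold, while Angptl4, an inhibitor of lipoprotein lipase, and the thioesterase Acot1 rose 2.35-fold and 2.49-fold. Ppara lost its edgeR call without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicate 3 (adjusted p = 0.0710, 0.103, 0.120 and 0.0734). Acsl1 had an edgeR adjusted p of 0.0735 and 0.0782 without Jag1+/+ replicates 2 and 3. Angptl4 lost its edgeR call without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicates 1 and 2 (adjusted p = 0.122, 0.0567, 0.133, 0.0606 and 0.0668). Acot1 had an edgeR adjusted p of 0.0567, 0.183, 0.194, 0.0587, 0.0717 and 0.0979 without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicates 1, 2 and 3. Ppara and Acot1 also lost their calls with sex as a covariate, in the deposited RPKM, with library totals alone and under quantile normalization, as did Acsl1 in the deposited RPKM, and Angptl4 with sex as a covariate, in the deposited RPKM with a pseudocount of 0.1, with the header factors dividing and with quality weights. In this list 4 genes rose without Jag1Ndr/Ndr replicate 3, the number that rose was 4 by DESeq2, and the number that fell 5 with quality weights and 4 by DESeq2. The list did not pass (camera adjusted p = 0.112, lower; median -0.36, mean 0.09), but was lower without Jag1Ndr/Ndr replicates 1 and 2 (adjusted p = 0.0410 and 0.0244). In the list of gluconeogenesis and glycolysis, 4 of 18 genes rose, 4 adjusted over the list alone, all of them glycolytic forms that prevail outside adult hepatocytes. Phosphofructokinase Pfkp rose from 4.96 ± 0.730 to 19.98 ± 7.13 CPM (edgeR adjusted p = 0.00836), aldolase Aldoa 2.42-fold, hexokinase Hk1 2.09-fold and pyruvate kinase Pkm 1.92-fold. Aldoa lost its edgeR call without Jag1+/+ replicates 1 and 2 (adjusted p = 0.0656 and 0.0698). Hk1 had an edgeR adjusted p of 0.0907, 0.114, 0.143, 0.0632 and 0.0731 without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicates 1 and 2. Pkm lost its edgeR call without Jag1+/+ replicates 1, 2 and 3 (adjusted p = 0.112, 0.106 and 0.0697). Hk1 also lost its call with sex as a covariate, in the deposited RPKM, with the header factors dividing and under quantile normalization, as did Pkm with sex as a covariate, in the deposited RPKM and with library totals alone. The list was higher (camera adjusted p = 0.00489; adjusted p = 0.331 with an estimated correlation).

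Of 17 acute phase genes 10 rose, 11 adjusted over the list alone. Lcn2, an iron-sequestering lipocalin, rose from 68.1 ± 5.56 to 632 ± 138 CPM (log2 fold change 3.22 ± 0.22, edgeR adjusted p = 0.000807), and Socs3, a feedback inhibitor of cytokine signalling, 4.53-fold. The serum amyloid genes Saa1 and Saa3, whose paralogs can share reads, rose 3.51-fold and 5.17-fold. This list was higher (camera adjusted p = 2.1e-07; adjusted p = 0.292 with an estimated correlation), and the number that rose was 5, 4 and 4 without Jag1+/+ replicates 1, 2 and 3. Cytokines, chemokines and adhesion molecules rose in 7 of 17 cases, 9 adjusted over the list alone (camera adjusted p = 8.4e-06; adjusted p = 0.317 with an estimated correlation). Cxcl1, which attracts neutrophils, rose 6.64-fold (edgeR adjusted p = 0.00722) and Ccl2, which attracts monocytes, 5.58-fold. Ccl2 had an edgeR adjusted p of 0.0518 without Jag1+/+ replicate 2, and the number of list genes that rose was 4, 1 and 2 without Jag1+/+ replicates 1, 2 and 3, and 4 without Jag1Ndr/Ndr replicate 1. In other settings it was 2 with sex as a covariate, 4 in the deposited RPKM with a pseudocount of 1 and with the stricter RPKM filter, and 3 with the header factors dividing.

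Markers of neutrophils and myeloid precursors were higher. Of 14, 8 rose over all genes and 14 adjusted over the list alone, with a median log2 fold change of 1.47 (camera adjusted p = 6.1e-10; adjusted p = 0.317 with an estimated correlation). Retnlg, a resistin-like peptide of neutrophils, rose from 6.17 ± 0.831 to 20.5 ± 2.29 CPM (edgeR adjusted p = 0.00270), the granulocyte growth factor receptor Csf3r 3.54-fold and the chemokine receptor Cxcr2 4.35-fold. The number of neutrophil markers past the threshold was 5, 3 and 3 without Jag1+/+ replicates 1, 2 and 3, and 13 without Jag1Ndr/Ndr replicate 1. Of 20 macrophage and monocyte markers 6 rose, 10 adjusted over the list alone (camera adjusted p = 1.7e-08; adjusted p = 0.292 with an estimated correlation). Gpnmb, a glycoprotein of lipid-laden macrophages, rose 7.42-fold (log2 fold change 2.89 ± 0.31, edgeR adjusted p = 0.00301). The number of macrophage markers that rose was 2, 1 and 2 without Jag1+/+ replicates 1, 2 and 3, and 2 with sex as a covariate and 10 by DESeq2, while that of neutrophil markers was 5 with sex as a covariate.

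**Figure D2:**
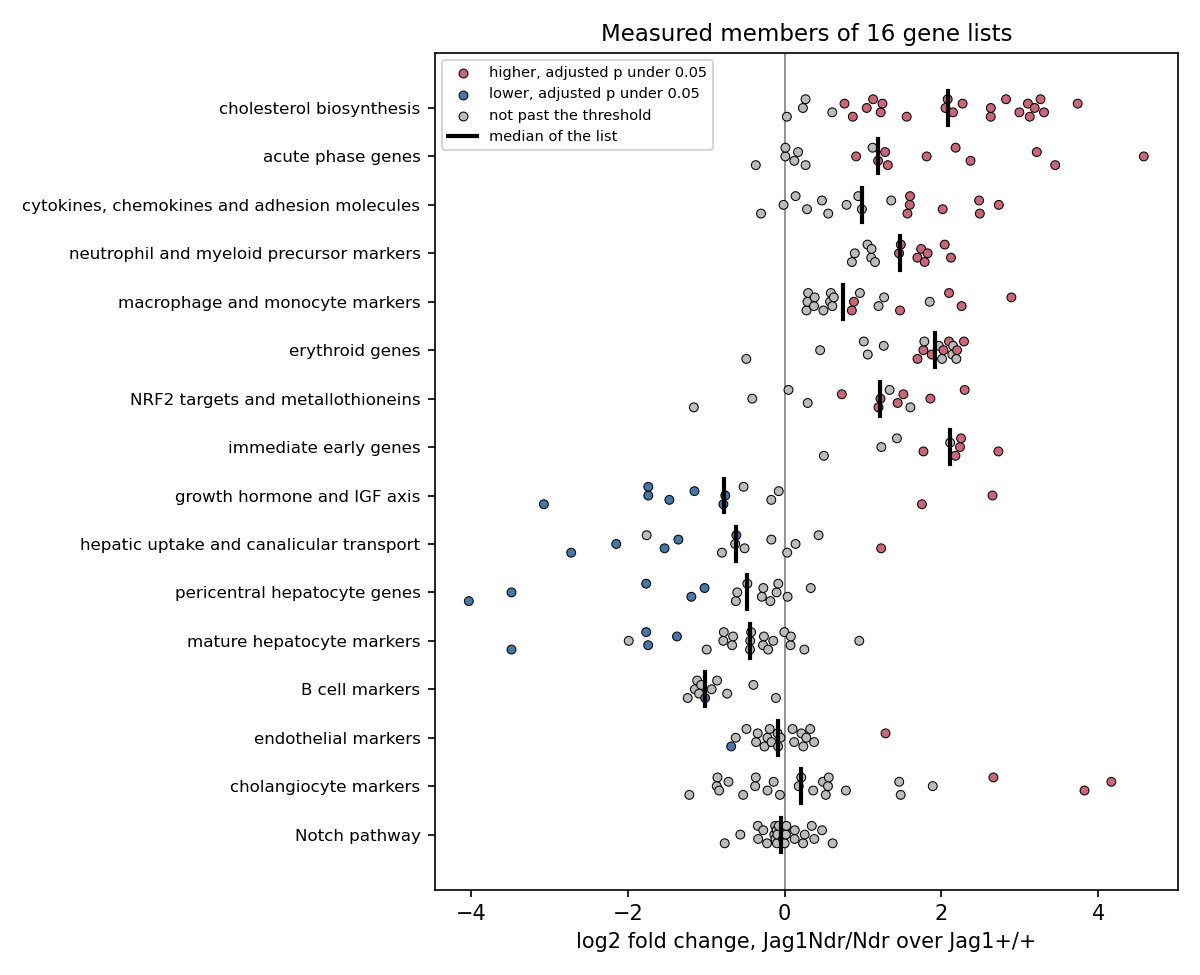
Log2 fold change (Jag1Ndr/Ndr over Jag1+/+, n = 3 each) of every measured member of 16 gene lists, with a point per gene, red and blue for genes higher and lower at an edgeR adjusted p under 0.05, grey for the rest, black bars for list medians and vertical offsets for display only. The medians lie at 2.08 for cholesterol biosynthesis, -0.77 for the growth hormone and IGF axis and -0.05 for the Notch pathway.

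Of 13 NRF2 targets and metallothioneins 7 rose over all genes, and adjusted over the list alone 9 were higher and 1 lower (camera adjusted p = 0.000254; adjusted p = 0.290 with an estimated correlation). Ugdh, which makes the sugar donor for glucuronidation, rose 2.86-fold (edgeR adjusted p = 0.00721) and the haem oxygenase Hmox1 2.72-fold. Hmox1 had an edgeR adjusted p of 0.0542 and 0.0568 without Jag1+/+ replicates 1 and 3. The number of list genes that rose was 2, 2 and 1 without Jag1+/+ replicates 1, 2 and 3, and 3 with the header factors dividing, while 1 fell without Jag1Ndr/Ndr replicate 2, as did 1 with the header factors dividing, with quality weights, without a filter and by DESeq2. Of 9 immediate early genes, which also respond to tissue handling, 5 rose, 8 adjusted over the list alone (camera adjusted p = 3.0e-07; adjusted p = 0.290 with an estimated correlation). Fos rose from 1.47 ± 0.940 to 9.29 ± 0.925 CPM (edgeR adjusted p = 0.00876), Atf3 4.53-fold, Junb 3.41-fold, Jun 4.76-fold and Nr4a1, chosen after its value was seen, 4.71-fold. Jun lost its edgeR call without Jag1+/+ replicate 2 (adjusted p = 0.0547). Nr4a1 had an edgeR adjusted p of 0.0871, 0.0738 and 0.0516 without Jag1+/+ replicates 2 and 3 and Jag1Ndr/Ndr replicate 3. The log2 fold change of Fos moved from 2.73 to 3.32 without Jag1+/+ replicate 1, and that of Nr4a1 from 2.24 to 2.89 without Jag1+/+ replicate 1. The number of immediate early genes past the threshold was 8 by DESeq2, and 3 without Jag1+/+ replicate 2.

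The p53 target list was higher (camera adjusted p = 0.0376; adjusted p = 0.295 with an estimated correlation), but not without Jag1+/+ replicate 1 or Jag1Ndr/Ndr replicate 2 or 3 (adjusted p = 0.147, 0.0895 and 0.123), in the deposited RPKM, without an expression filter or with library totals alone. For its genes edgeR gave 0 of 9 members past the threshold over all genes and 3 adjusted over the list alone, with 5 at an unadjusted p under 0.05, 3 by DESeq2 and 2 by limma with quality weights. The apoptosis effector Bax had a log2 fold change of 0.60 ± 0.16 and the stress cytokine Gdf15 of 1.65 ± 0.54 (edgeR adjusted p = 0.0589 and 0.107). Bax passed by DESeq2 and with quality weights (adjusted p = 0.0243 and 0.0373), and Gdf15 by DESeq2 and without Jag1Ndr/Ndr replicate 3 (adjusted p = 0.0151 and 0.0322), where 1 gene of the list passed. Of 16 genes of the unfolded protein and amino acid response, the pseudokinase Trib3 rose 2.99-fold (edgeR adjusted p = 0.0327), with 2 higher adjusted over the list alone. Trib3 lost its edgeR call without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicate 3 (adjusted p = 0.117, 0.127, 0.0799 and 0.0504). Trib3 also lost its call with the header factors dividing and under quantile normalization. That list did not pass (camera adjusted p = 0.0547), but was higher without Jag1Ndr/Ndr replicate 3 (adjusted p = 0.00137), in the deposited RPKM, with the stricter RPKM filter, under quantile normalization, with library totals alone and with sex as a covariate. The number of its genes that rose was 2 without a filter and by DESeq2.

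Hepatocyte genes of the growth hormone and IGF axis were lower. Of 12, 7 fell and 2 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.000209, lower; adjusted p = 0.290 with an estimated correlation). Igfals (chromosome 17, positions 24877844 to 24882011) had a log2 fold change of -3.07 ± 0.23 (edgeR adjusted p = 0.000880), and the growth hormone receptor Ghr fell from 392 ± 32.9 to 117 ± 38.5 CPM. The prolactin receptor Prlr fell 3.33-fold. The IGF-binding protein genes Igfbp1 and Igfbp2, the latter chosen after its value was seen, rose 6.28-fold and 3.37-fold. Igfbp1 had an edgeR adjusted p of 0.0544 without Jag1+/+ replicate 2. Igfbp2 lost its edgeR call without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicate 1 (adjusted p = 0.149, 0.113, 0.188 and 0.0594). Igfbp2 also lost its call with sex as a covariate, with the header factors dividing, under median rescaling and with quality weights. The log2 fold change of Igfbp2 moved from 1.75 to 1.13 without Jag1Ndr/Ndr replicate 1. The number that fell was 4 each without Jag1+/+ replicates 1 and 2, and 4 in the deposited RPKM and with library totals alone.

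Mature hepatocyte markers were lower as a list (camera adjusted p = 5.0e-05; adjusted p = 0.512 with an estimated correlation), with 4 of 22 falling over all genes and adjusted over the list alone. Cyp1a2, an oxidase of drugs and caffeine, fell from 352 ± 91.5 to 31.5 ± 4.68 CPM (log2 fold change -3.48 ± 0.25, edgeR adjusted p = 0.000818), the glucuronosyltransferase Ugt2b1 3.34-fold, Cyp2e1 3.40-fold and the thyroid hormone carrier Ttr 2.59-fold. Of these markers 8 fell without Jag1Ndr/Ndr replicate 1, 1 rose without Jag1Ndr/Ndr replicate 2, and the number that fell was 7 with quality weights. Alb had a log2 fold change of -0.66 ± 0.28 that did not pass (edgeR adjusted p = 0.214), except without Jag1Ndr/Ndr replicate 1 (-0.92, adjusted p = 0.0324), in DESeq2, with quality weights and with library totals alone. Pericentral genes, some of them also on the former list, fell in 5 of 15 cases, 6 adjusted over the list alone (camera adjusted p = 7.6e-06; adjusted p = 0.292 with an estimated correlation). Besides Cyp1a2 and Cyp2e1 these were glutamine synthetase Glul (2.28-fold), Rgn (2.03-fold) and the glutamate transporter Slc1a2 (16.3-fold), the last chosen after its value was seen. Ttr, Rgn and Slc1a2 lost their edgeR calls without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicate 3 (adjusted p = 0.0962, 0.101, 0.104 and 0.0697 for Ttr, 0.0902, 0.0871, 0.108 and 0.0648 for Rgn, and 0.0912, 0.109, 0.0882 and 0.0949 for Slc1a2). Glul lost its edgeR call without Jag1+/+ replicates 1 and 2 and Jag1Ndr/Ndr replicate 3 (adjusted p = 0.0901, 0.0982 and 0.0570). Ttr also lost its call with the header factors dividing, as did Glul in the deposited RPKM, with library totals alone and under quantile normalization, and Rgn in the deposited RPKM and with the header factors dividing. The log2 fold change of Slc1a2 moved from -4.03 to -5.86 and -3.16 without Jag1Ndr/Ndr replicates 1 and 2.

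Of 14 periportal genes only the lipid droplet protein gene Hsd17b13 rose (1.72-fold, edgeR adjusted p = 0.0499), with 0 adjusted over the list alone. Hsd17b13 had an edgeR adjusted p of 0.180, 0.0929, 0.238, 0.0660 and 0.0965 without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicates 1 and 3. Hsd17b13 also lost its call with sex as a covariate, with the header factors dividing, under median rescaling, with quality weights, with robust moderation and without a filter. For the periportal list edgeR counted 4 at an unadjusted p under 0.05 and DESeq2 called 1. It did not pass (camera adjusted p = 0.760, lower; median 0.03, mean 0.01), and its direction was higher with sex as a covariate, with the header factors dividing, under quantile normalization, with the stricter RPKM filter and without Jag1+/+ replicate 3 or Jag1Ndr/Ndr replicate 2. In that list 2 genes rose without Jag1Ndr/Ndr replicate 2, 2 fell without Jag1Ndr/Ndr replicate 3, and the number that rose was 2 in the deposited RPKM with a pseudocount of 0.5 and 1 and with quality weights. In the fetal hepatocyte list, 2 of 14 rose and 1 fell, over all genes and adjusted over the list alone, without passing as a list (camera adjusted p = 0.206), though it was higher without Jag1Ndr/Ndr replicate 1 (adjusted p = 0.0406). Bex1 rose from 3.26 ± 1.16 to 34.0 ± 18.8 CPM (edgeR adjusted p = 0.00836) and alpha-fetoprotein Afp 5.68-fold, while the growth-restraining imprinted gene Cdkn1c fell 3.18-fold. Afp lost its edgeR call without Jag1+/+ replicates 1 and 3 (adjusted p = 0.103 and 0.0784). Afp also lost its call with sex as a covariate and with quality weights, as did Cdkn1c in the deposited RPKM with a pseudocount of 0.1.

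Transporters of hepatic uptake and canalicular secretion were lower as a list (camera adjusted p = 0.000371; adjusted p = 0.290 with an estimated correlation), with 5 of 14 falling and 1 rising over all genes, and 9 and 2 adjusted over the list alone. The organic anion transporter Slco1a4 fell from 53.5 ± 30.6 to 8.11 ± 1.93 CPM (log2 fold change -2.72 ± 0.39, edgeR adjusted p = 0.00776) and Slc22a7 4.43-fold. Abcg5 and Abcg8, which together export sterols and whose genes overlap, fell 2.89-fold and 2.56-fold. Abcg2, an exporter of xenobiotics, fell 1.53-fold and Abcb4, which moves phospholipid into bile, rose 2.35-fold, both chosen after their values were seen. Abcg2 had an edgeR adjusted p of 0.153, 0.101, 0.134, 0.0519, 0.0808 and 0.0870 without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicates 1, 2 and 3. Abcb4 lost its edgeR call without Jag1+/+ replicates 1, 2 and 3 (adjusted p = 0.0656, 0.0802 and 0.0568). Abcg8 also lost its call in the deposited RPKM, as did Abcg2 with sex as a covariate, in the deposited RPKM, with library totals alone, with the header factors dividing, under quantile normalization and with quality weights. The bile salt export pump Abcb11 and the bile acid uptake carrier Slc10a1 had log2 fold changes of 0.43 ± 0.18 and 0.03 ± 0.20 (edgeR adjusted p = 0.193 and 0.948), and that of Slc10a1 was -0.10 and -0.06 without Jag1+/+ replicate 1 and Jag1Ndr/Ndr replicate 1.

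Bile acid synthesis genes divided, 4 of 14 falling and 1 rising over all genes, and 4 and 3 adjusted over the list alone, without passing as a list (camera adjusted p = 0.143). The steroid reductase Akr1d1 fell from 367 ± 31.8 to 149.5 ± 30.7 CPM (log2 fold change -1.30 ± 0.20, edgeR adjusted p = 0.00925). Acox2, of side chain oxidation, fell 1.74-fold, Scp2, a sterol carrier, 1.68-fold and the steroid dehydrogenase Hsd3b7, chosen after its value was seen, 1.87-fold. Baat, which conjugates bile acids to amino acids, rose 4.67-fold. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of -0.68 ± 0.51 that did not pass (edgeR adjusted p = 0.495). Acox2 and Hsd3b7 lost their edgeR calls without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicates 2 and 3 (adjusted p = 0.0901, 0.103, 0.176, 0.0637 and 0.0785 for Acox2, and 0.0971, 0.148, 0.143, 0.0592 and 0.0757 for Hsd3b7). Scp2 lost its edgeR call without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicate 3 (adjusted p = 0.126, 0.114, 0.161 and 0.0597). Baat had an edgeR adjusted p of 0.0624 and 0.0565 without Jag1+/+ replicates 1 and 2. Akr1d1 also lost its call in the deposited RPKM, as did Acox2 with sex as a covariate, in the deposited RPKM, with library totals alone and with the header factors dividing, Hsd3b7 with sex as a covariate, in the deposited RPKM and with the header factors dividing, and Scp2 with sex as a covariate, in the deposited RPKM, with library totals alone, with the header factors dividing and under quantile normalization. Of the list, 3 rose without Jag1Ndr/Ndr replicate 2, and the number that rose was 3 with quality weights and 2 by DESeq2. Of 13 efflux and detoxification genes known to be induced in cholestasis, 1 rose and 2 fell, 3 and 2 adjusted over the list alone. Slc51b, a subunit of the basolateral bile acid exporter, rose 2.84-fold, while Cyp2b10 and the sulfotransferase Sult2a8, listed as 2810007J24Rik, fell 20.8-fold and 6.87-fold. Slc51b lost its edgeR call without Jag1+/+ replicates 1, 2 and 3 (adjusted p = 0.0656, 0.0808 and 0.0696). The list did not pass (camera adjusted p = 0.819, higher), with a median of 0.47, a mean of -0.21 and a lower direction in the deposited RPKM, with the stricter RPKM filter and without Jag1Ndr/Ndr replicates 1 or 2. By DESeq2 and with quality weights 2 of its genes rose.

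Erythroid genes were higher in Jag1Ndr/Ndr livers, 7 of 18 rising over all genes and 15 adjusted over the list alone, with a median log2 fold change of 1.92 (camera adjusted p = 1.7e-08; adjusted p = 0.411 with an estimated correlation). The red cell anion exchanger Slc4a1 rose from 42.2 ± 22.0 to 180.1 ± 86.2 CPM, and the blood group genes Kel and Ermap 4.88-fold and 4.59-fold, with edgeR adjusted p-values from 0.0253 to 0.0393. The mean of the list relative to the Jag1+/+ mean, on the log2 scale, was 0.67, -0.04 and -0.63 in the Jag1+/+ and 2.01, 2.05 and 0.81 in the Jag1Ndr/Ndr libraries. By edgeR the number of erythroid genes past the threshold was 0 each without Jag1+/+ replicates 2 and 3, and 0, 0 and 13 without Jag1Ndr/Ndr replicates 1, 2 and 3, with 0 when sex was a covariate. In each of these 5 fits with 0, 15 genes had an unadjusted p under 0.05, and over all 6 libraries DESeq2 called 15 and limma with quality weights 8. The count was 1 with the header factors dividing and 12 without a filter. It was 16 with a block for the replicate number, whose meaning the labels do not give. Kel and Slc4a1 lost their edgeR calls without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicates 1 and 2 (adjusted p = 0.0671, 0.0971, 0.0996, 0.0546 and 0.0523 for Kel, and 0.0595, 0.136, 0.115, 0.0805 and 0.0754 for Slc4a1). Ermap lost its edgeR call without Jag1+/+ replicates 2 and 3 and Jag1Ndr/Ndr replicates 1 and 2 (adjusted p = 0.105, 0.0809, 0.0507 and 0.0534). Kel also lost its call with sex as a covariate and with the header factors dividing, as did Ermap with sex as a covariate, and Slc4a1 with sex as a covariate, with the header factors dividing and with quality weights. Megakaryocyte and platelet genes were higher as a list (camera adjusted p = 0.00177; adjusted p = 0.565 with an estimated correlation), though edgeR gave 0 of 8 members past the threshold over all genes and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma with quality weights. The platelet integrin Itga2b had a log2 fold change of 1.29 ± 0.37 (edgeR adjusted p = 0.0742). It was the 1 gene that passed without Jag1Ndr/Ndr replicate 3, without a filter and by DESeq2 (adjusted p = 0.0291, 0.0467 and 0.00659). With the replicate block 6 of the 8 megakaryocyte genes rose.

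B cell markers were lower as a list (camera adjusted p = 0.000521; adjusted p = 0.565 with an estimated correlation), with a median log2 fold change of -1.01. The antigen receptor component Cd79b fell from 22.5 ± 3.69 to 10.98 ± 3.44 CPM (log2 fold change -1.01 ± 0.25, edgeR adjusted p = 0.0452) and was the only 1 of 11 past the threshold, over all genes and adjusted over the list alone. Cd79b had an edgeR adjusted p of 0.142, 0.0808, 0.143, 0.0607 and 0.101 without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicates 1 and 3. Cd79b also lost its call in the deposited RPKM, with library totals alone and with the stricter RPKM filter. The mean of the B cell list was 0.04, -0.27 and 0.23 in the Jag1+/+ and -2.57, -0.21 and -1.09 in the Jag1Ndr/Ndr libraries, so the genotypes overlapped, and 2 markers fell without Jag1Ndr/Ndr replicate 2. The number that fell was 3 by DESeq2. For T and NK cell markers edgeR gave 0 of 13 members past the threshold over all genes and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma with quality weights, and that list did not pass (camera adjusted p = 0.494, higher, and lower without Jag1Ndr/Ndr replicate 2).

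Of 34 extracellular matrix and fibrosis genes 2 rose, with 4 higher and 1 lower adjusted over the list alone. Timp1, an inhibitor of matrix proteases, rose from 0.757 ± 0.456 to 14.5 ± 5.95 CPM (log2 fold change 4.35 ± 0.48, edgeR adjusted p = 0.00314), while the number of list genes that rose was 8 without Jag1Ndr/Ndr replicate 1, and 8 with quality weights and 7 by DESeq2. By DESeq2 1 fell. Collagen Col1a1 had a log2 fold change of 0.63 ± 0.23 that did not pass (edgeR adjusted p = 0.151). The list was higher (camera adjusted p = 0.0361; adjusted p = 0.679 with an estimated correlation), but not without Jag1+/+ replicates 2 and 3 or Jag1Ndr/Ndr replicates 2 and 3 (adjusted p = 0.0783, 0.0641, 0.165 and 0.129), nor with library totals alone or sex as a covariate. Of 17 stellate cell, fibroblast and smooth muscle markers the matrix protein Reln fell 1.74-fold (edgeR adjusted p = 0.0361), with 1 higher and 2 lower adjusted over the list alone, and Acta2 of contractile cells stood at 0.69 ± 0.48. Of 20 endothelial markers Vwf, of blood clotting, rose 2.44-fold and Dnase1l3, a secreted nuclease, fell 1.60-fold, over all genes and adjusted over the list alone. Reln lost its edgeR call without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicates 1 and 3 (adjusted p = 0.101, 0.138, 0.134, 0.0547 and 0.0849). Dnase1l3 had an edgeR adjusted p of 0.0860, 0.147, 0.143, 0.0599 and 0.0820 without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicates 2 and 3. Reln also lost its call with sex as a covariate, in the deposited RPKM, with library totals alone and under quantile normalization, as did Dnase1l3 with sex as a covariate, in the deposited RPKM, with library totals alone and with the header factors dividing, and Vwf in the deposited RPKM. Among stellate markers 1 rose without Jag1Ndr/Ndr replicates 1 or 3, and 2 fell without Jag1Ndr/Ndr replicate 2, while 2 endothelial markers fell without Jag1Ndr/Ndr replicate 1, as did 2 with quality weights. In other settings the number of stellate markers that rose was 1 with quality weights and by DESeq2, and the number that fell 2 with quality weights, without a filter and by DESeq2. Neither list passed (camera adjusted p = 0.571 for both), and the stellate direction turned from higher to lower without Jag1Ndr/Ndr replicate 2.

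For arterial endothelial markers edgeR gave 0 of 8 members past the threshold over all genes and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma with quality weights (camera adjusted p = 0.440), while 1 rose without Jag1Ndr/Ndr replicate 1. For cell cycle genes it gave 0 of 28 members past the threshold over all genes and 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma with quality weights, and the list, at a median of 0.19, did not pass (camera adjusted p = 0.0906) but was higher without Jag1+/+ replicate 3 or Jag1Ndr/Ndr replicate 1 or 3 (adjusted p = 0.0246, 0.0406 and 0.00288), and turned lower without Jag1Ndr/Ndr replicate 2. For interferon response genes it gave 0 of 19 members past the threshold over all genes and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma with quality weights, and the list did not pass (camera adjusted p = 0.143) but was higher without Jag1Ndr/Ndr replicate 3 (adjusted p = 0.0407). Of its genes 1 rose without Jag1Ndr/Ndr replicates 2 or 3 and 1 fell without Jag1Ndr/Ndr replicate 2. For YAP targets it gave 0 of 8 members past the threshold over all genes and 0 adjusted over the list alone, with 3 at an unadjusted p under 0.05, 1 by DESeq2 and 1 by limma with quality weights (camera adjusted p = 0.571, higher, and lower without Jag1Ndr/Ndr replicate 2).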

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

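The deposited RPKM with a pseudocount of 0.5, the header factors dividing, library totals without TMM and the sex covariate were chosen after the data were seen. Against 1054 changed genes (653 higher, 401 lower), the deposited RPKM gave 440 changed, 350 higher and 90 lower with a pseudocount of 0.1, 469 changed, 371 higher and 98 lower with 1 and 469 changed, 372 higher and 97 lower with 0.5. The header factors dividing gave 692 changed and 387 higher, library totals alone 210 lower and the sex covariate 596 changed, 366 higher and 230 lower. Quality weights gave 1594 changed and 644 lower, and DESeq2 1866 changed, 1127 higher and 739 lower. In each of these settings, no gene called by edgeR and tested there had the other sign. Leaving out each library gave 282 to 1211 changed, 155 to 679 higher and 127 to 532 lower, 11 to 15 lists higher and 6 to 8 lower, and Jag1 log2 fold changes of -0.45 to -0.06. With an estimated correlation, 0 lists were higher and 0 lower by camera, with 5 at an unadjusted p under 0.05 and 11 called by fry. The other counts moved by less than 1.5 times. Jag1 turned to 0.0122 in the deposited RPKM with a pseudocount of 1. Hes1 turned to 0.11, 0.12 and 0.11 in the deposited RPKM with 0.1, 1 and 0.5, to 0.14 with library totals, and to 0.11, 0.18 and 0.12 without Jag1+/+ replicate 2 and Jag1Ndr/Ndr replicates 1 and 3. Dtx4 (main value -0.12) turned to 0.13, 0.12, 0.13, 0.00568 and, without Jag1+/+ replicate 2, 0.0633. Epcam turned to 0.0158, 0.10 and 0.17 without Jag1+/+ replicate 1 and Jag1Ndr/Ndr replicates 1 and 2, Slc10a1 to -0.10 and -0.0571 without Jag1+/+ replicate 1 and Jag1Ndr/Ndr replicate 1, and Eif2s3y to 0.18 with the sex covariate. These 6 genes did not pass in any of the settings. Of 3794 values of the 192 named genes besides Jag1, 3356 kept direction and side of the threshold, 351 lost the call, 69 gained it and 18 changed sign. The sign changes are those of Hes1, Dtx4, Epcam, Slc10a1 and Eif2s3y just given. Over the leave-one-out fits, Hes1 lay between -0.51 and 0.18, Dtx4 between -0.24 and 0.0633, Epcam between -1.36 and 0.17 and Slc10a1 between -0.10 and 0.15. Quantile normalization fixes the most abundant gene, so it gives no value for Alb. The cause of these moves was not tested. The leave-one-out fits all had fewer libraries, yet their counts differed by genotype. Changed genes numbered 342, 282 and 319 without Jag1+/+ replicates 1, 2 and 3. They numbered 1211, 1034 and 890 without Jag1Ndr/Ndr replicates 1, 2 and 3. Pairs of libraries differed by a chi-square over its degrees of freedom of 22.1, 30.6 and 33.7 within Jag1+/+. Within Jag1Ndr/Ndr it was 122, 64.5 and 114, a measure that also grows with depth.

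The labels give the libraries of a replicate number a shared prefix, 1 library per genotype, without saying what it marks, so pairing by litter, batch or day is not stated. After removal of the genotype means, libraries with the same replicate number correlated at 0.0856, 0.170 and 0.195, not all above 0.1, and with other numbers at -0.0188 at most. That removal makes the deviations within a genotype cancel out, so positive same-number values push the others below them. Every library of a genotype correlated best with its own number in the other genotype, but this is a weak hint from the data and not the design. A block for the replicate number gave 1430 changed, 843 higher and 587 lower, with 16 erythroid genes higher against 7, 6 of 8 megakaryocyte genes against 0, 4 fatty acid oxidation genes against 2 and 4 clock genes lower against 2. Under it the only B cell call, Cd79b, and the only periportal call, Hsd17b13, were lost (adjusted p = 0.0543 and 0.0592), and Itga2b and Bax passed (0.00752 and 0.0469).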

Other observations

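The tests of the erythroid, chromosome 2 and RPKM patterns, and the settings with sex as a covariate, library totals alone and the deposited RPKM with a pseudocount of 0.5, were chosen after the results were seen, while the splits of the libraries were planned. Circadian clock genes were lower as a list (camera adjusted p = 0.00631; adjusted p = 0.566 with an estimated correlation), with 2 of 15 falling over all genes and 3 adjusted over the list alone. The clock-output factor Hlf fell from 63.0 ± 3.20 to 26.6 ± 6.30 CPM (log2 fold change -1.24 ± 0.19, edgeR adjusted p = 0.00956) and the period gene Per3 2.39-fold. Per3 lost its edgeR call without Jag1+/+ replicates 1, 2 and 3 (adjusted p = 0.0710, 0.0667 and 0.104). Hlf also lost its call in the deposited RPKM and with library totals alone, as did Per3 with sex as a covariate, in the deposited RPKM and with library totals alone. Without Jag1Ndr/Ndr replicate 2 and by DESeq2, 1 clock gene was higher. Time of collection is not given in the labels.

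Mesothelial genes were higher as a list (camera adjusted p = 0.0109; adjusted p = 0.565 with an estimated correlation), though not under the stricter RPKM filter, and edgeR gave 0 of 6 members past the threshold over all genes and 1 adjusted over the list alone, with 2 at an unadjusted p under 0.05, 1 by DESeq2 and 1 by limma with quality weights. Wt1, a transcription factor of the mesothelium, had a log2 fold change of 1.69 ± 0.45 (edgeR adjusted p = 0.0577, and 0.0309 without Jag1Ndr/Ndr replicate 1, 0.0136 by DESeq2, 0.0233 with quality weights and 0.0469 without a filter). Of 12 further liver and bile duct transcription factors only the epithelial factor Ehf fell (5.87-fold, edgeR adjusted p = 0.0196), with 2 lower adjusted over the list alone. Ehf had an edgeR adjusted p of 0.0575, 0.0962, 0.0544 and 0.0686 without Jag1+/+ replicates 1, 2 and 3 and Jag1Ndr/Ndr replicate 2. Ehf also lost its call with sex as a covariate. In this list 2 genes fell under median rescaling, without a filter and by DESeq2. That list did not pass (camera adjusted p = 0.112), but was lower without Jag1Ndr/Ndr replicate 3 (adjusted p = 0.00912), with sex as a covariate and without a filter. Of the adipocyte list, too short to test with 2 measured genes, the lipid droplet gene Cidea rose from 0.0496 ± 0.0208 to 1.05 ± 0.147 CPM (edgeR adjusted p = 0.00353; also adjusted over the list alone), and Plin4 had a log2 fold change of 0.57 ± 0.46. The single measured genes of exocrine pancreas and skeletal muscle, Cela2a and Mylpf, had log2 fold changes of -0.42 ± 0.46 and 1.14 ± 0.52 (edgeR adjusted p = 0.666 and 0.242).

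The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The genotypes gave 1054 changed genes against 4 at most in another split, 653 higher against 3, and 401 lower against 3, so that 1 split, the real one, gave counts as large. In the other splits direction is arbitrary, so the larger side was counted there. For lists that side held 16 at most, against 13 higher and 6 lower for the genotypes. By that count 2 splits reached 13 and 8 reached 6, the real split included. The latter sets the smaller real side against larger sides, so it decides nothing about the lower lists. With Jag1Ndr/Ndr replicate 3 grouped with Jag1+/+ replicates 1 and 2, or 1 and 3, the directions held 11 and 7, or 12 and 6, lists. With Jag1+/+ replicate 1 grouped with Jag1Ndr/Ndr replicates 1 and 2, they held 5 and 16. That mixed split called more lists in all than the genotypes did, though it changed 0 genes.

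The erythroid list lay 2.01 above the endothelial list in median log2 fold change (bootstrap 95% interval over genes 1.55 to 2.25). Intervals over genes leave out the spread between libraries. Relative to the Jag1+/+ mean, on the log2 scale, the endothelial list stood at 0.0013, 0.07 and -0.08 in the Jag1+/+ libraries. In the Jag1Ndr/Ndr libraries it stood at -0.03, -0.01 and -0.09. A lower share of hepatocytes would raise other cell types alike, so these values argue against it as the whole cause. A uniform delay of liver development, with more of the blood formation of the newborn liver, could raise erythroid genes. It would raise B cell precursor and fetal hepatocyte genes too. The B cell median was -1.01 (-1.11 to -0.73), yet Jag1Ndr/Ndr replicate 2 lay within the Jag1+/+ range. The fetal hepatocyte median was 0.35, and that list did not pass (camera adjusted p = 0.206). Such a delay thus stays open. With sex as a covariate the call of Slc4a1 ended (edgeR adjusted p = 0.0393 before and 0.0771 after), with a log2 fold change of 2.10 ± 0.49 before and 2.07 ± 0.52 after, and what ended the call was not tested. The genotype itself is a biological explanation that was not tested apart from a delay.

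A segment of C3H origin carried with the Ndr allele may change genes around Jag1. Within 20 Mb of Jag1 24 of 318 genes changed (7.55%, and 7.63% elsewhere), an odds ratio of 0.989 (Fisher's exact 95% interval 0.620 to 1.51). The window ranked 32 of 71 windows of 40 Mb. The interval does not exclude a modest excess. The test counts changed genes and does not weigh the size of a change, so it cannot show whether the largest rises cluster near Jag1. A segment thus stays open, and no biological explanation was tested.

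The library medians of the deposited RPKM spread apart, with an SD of 0.393 on the log2 scale, against 0.164 without the header factors and 0.0773 with the factors dividing. The spread as deposited was 5.09 times that with the factors dividing. The header factors correlated with edgeR's TMM factors at a Pearson r of 0.992. The deposited RPKM were thus multiplied by factors by which edgeR divides. No biological explanation was tested.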
